A study of Homo sapiens with 6 samples.

How the data were processed

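Total RNA of WM451-Lu melanoma cells infected with a lentivirus for GFP or for SETDB1 was measured on 6 Affymetrix whole-transcript gene arrays, 3 per group. Per the labels' protocols, cells grew on gelatin-coated plates, infection lasted 24 h, RNA was taken after 48 h and purified on RNeasy columns, and the design text gives 2 days of growth. Groups and replicate numbers came from the sample titles. The authors' deposited table holds log2 values of 33297 probe sets in the 6 arrays, made with RMA per the submitters' processing notes, whose version is not given in the sources used here. RMA subtracts background, equalises the distribution of probe intensities between arrays and summarises the probes of a probe set on the log2 scale, so a change of most transcripts in 1 direction would be hidden and changes of dim genes are compressed. Intensities of single probes were not used here, and signal over background could not be given per probe set.

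A table of the array's annotation paired 21214 probe sets with genes, 19460 with a single gene symbol and 1754 with several. The remaining 12083 are unnamed here. Of the single ones, 19429 matched a gene of RefSeq by Entrez number, and no symbol changed by the update. No gene was named from a probe set with several. For 769 genes with several probe sets the one with the highest mean over the 6 arrays was taken, which left 18417 genes. No genome build was given with the values, so no coordinates are printed. Probe sets can cross-hybridise between near-identical genes, as in the histone, small nuclear and small nucleolar RNA families.

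The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, with no intensity trend and no block), and p-values were adjusted by Benjamini-Hochberg over the genes tested. The tests were two-sided. Calls were made at an adjusted p of 0.05, and counts are also given for changes of at least 1.5-fold. The prior added 4.18 degrees of freedom. Fold changes are differences of mean log2 values, SETDB1 minus GFP.

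Before the data were examined, 26 gene lists were fixed with the test for them, the alternatives and the rule for named genes. The lists are the HOX cluster, HOX cofactors, machinery of H3K9 methylation, zinc finger genes with ZNF symbols, clustered protocadherins beta, cancer-testis antigens, melanocyte differentiation and pigmentation, neural crest and undifferentiated melanoma, interferon-stimulated genes, the inflammatory and NF-kB response, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, p53 targets and senescence, MAPK pathway output, the unfolded protein and integrated stress response, heat shock proteins, cholesterol biosynthesis and uptake, hypoxia and glycolysis, extracellular matrix and TGF-beta response, cytosolic ribosomal proteins, oxidative phosphorylation subunits, and markers of keratinocytes, fibroblasts, endothelial cells and leukocytes. The HOX list followed what is known of the study; the others came from general knowledge. Lists were tested with limma's camera, which compares a list with all other genes, at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26 lists. Camera with a correlation estimated from the data and fry were run as alternatives. Medians were also placed among those of 10000 random lists of equal size, matched on mean level in 50 bins, a comparison not fixed beforehand. The counts of called members are given over all genes and adjusted over the list alone.

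The text names SETDB1 first, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, and of each list up to 4 members with the smallest p, with every called member of the HOX list. Any other gene is said to have been chosen after its values were seen. The classes of small RNA genes follow RefSeq's biotypes.

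Alternatives fixed before the data were examined were the replicate number as a block, leaving out each array in turn, centring arrays on their medians, quantile normalization, an intensity trend with a robust prior, array weights, a filter on genes below the median probe set level, all probe sets tested, the mean of a gene's probe sets, other thresholds, and list members above the median level only. Cyclic loess between arrays, protein-coding genes only and the class tests were chosen after seeing the data. Genes whose level can reveal a person's sex are not reported.

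The procedure was tested on simulated data with 200 changed genes among 18417, drawn for the comparison of SETDB1 with GFP. It recovered 74% of genes changed by a log2 value of 0.5 and 98% of those changed by 1, and 2.82% of its calls were unchanged genes. With no simulated change it called 0 genes and 0 lists. The noise was drawn for each gene independently, so the simulation cannot show how camera behaves when the genes of a list vary together.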

Results

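The data were microarray profiles of total RNA from WM451-Lu, a human melanoma culture that the labels also call a cell line. The cells had been infected with a lentivirus carrying either SETDB1, an enzyme that methylates histone H3 at a lysine linked to gene silencing, or green fluorescent protein (GFP), the control. Each group had 3 arrays. Infection lasted 24 h and RNA was taken after 48 h. The median log2 value of an array lay between 6.67 and 6.78. Across probe sets, Pearson's r was 0.994 to 0.996 between GFP arrays, 0.996 to 0.997 between SETDB1 arrays and 0.992 to 0.995 between groups. The comparison of the groups asks which transcripts differ when the cells carry extra SETDB1. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

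SETDB1 itself (Entrez gene 9869) was 2.64-fold higher in the SETDB1 arrays. Its log2 value was 8.49 ± 0.05 (SD, n = 3) with GFP and 9.89 ± 0.14 (SD, n = 3) with SETDB1, a log2 fold change of 1.40 (95% interval 1.22 to 1.58, limma adjusted p = 0.000677). It was higher in each of the 3 SETDB1 arrays than in any GFP array, and without each array in turn the log2 fold change stayed between 1.33 and 1.47. SETDB1 was the only gene that rose by at least 2-fold, while 10 genes fell by that much. Of 18417 genes tested, 674 rose and 1389 fell past the adjusted threshold of 0.05, but most of these changes were small. At least 1.5-fold, 17 genes rose and 138 fell, and 59 of the latter are listed as other than protein-coding.

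The counts of small changes fell whichever array was left out and moved with scaling. The total of 2063 genes became 1372, 1169 and 1700 without GFP replicates 1, 2 and 3. It became 861, 556 and 888 without SETDB1 replicates 1, 2 and 3. Each of these fits has fewer arrays and is less able to detect small changes. A call lost in such a fit, here and below, therefore need not mean that the change rested on that array. Centring each array on its median gave 347 higher and 1767 lower genes, and quantile normalization gave 846 higher and 1100 lower genes. In 6678 genes (36.3%) the groups did not overlap, where chance gives 10%.

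Besides SETDB1, CXCL8 and MYOF rose most. CXCL8, the chemokine interleukin-8, rose 1.93-fold (log2 fold change 0.95, SE 0.07, adjusted p = 0.00215), from 7.31 ± 0.10 to 8.25 ± 0.07 (SD, n = 3 each). MYOF, which encodes the membrane repair protein myoferlin, rose 1.87-fold (log2 fold change 0.90, SE 0.08, adjusted p = 0.00246). The arrestin-domain genes ARRDC4 and ARRDC3 rose 1.67-fold and 1.63-fold. ACTA2, the smooth muscle actin, rose 1.67-fold, and TAS2R5, a taste receptor, rose 1.65-fold. The remaining genes of the 10 with the largest rise were KCNJ2, a potassium channel (1.61-fold), KLF10, a transcription factor induced by TGF-beta (1.60-fold), CA2, a carbonic anhydrase (1.58-fold), and EREG, the EGF receptor ligand epiregulin (1.57-fold). Each of the 10 was higher in all 3 SETDB1 arrays than in any GFP array, which the rule for naming them required. Each also kept its call without each array in turn.

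**Figure D1:**
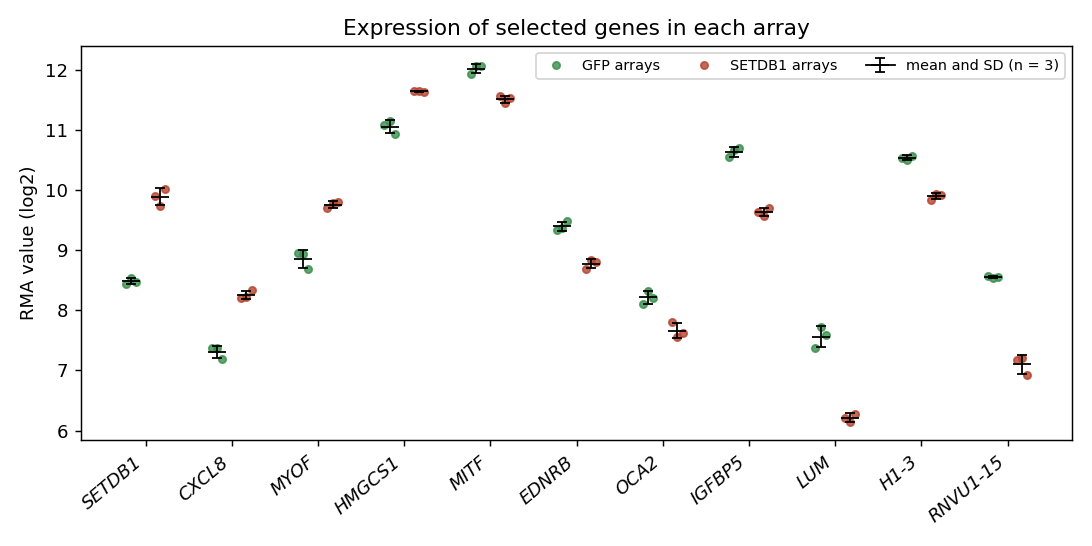
RMA values (log2, vertical axis) of 11 genes (horizontal axis) in the 3 GFP arrays (green) and the 3 SETDB1 arrays (red), with the mean and SD of each group. The groups do not overlap in any of these genes, which holds for every gene past the adjusted threshold. SETDB1 rises from 8.49 to 9.89 while LUM falls from 7.56 to 6.21.

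Of the 10 genes that fell most, LUM, BCHE and IGFBP5 encode proteins. LUM, the matrix proteoglycan lumican, was 2.55-fold lower, at 7.56 ± 0.17 with GFP and 6.21 ± 0.07 with SETDB1 (SD, n = 3 each; log2 fold change -1.35, SE 0.09, adjusted p = 0.00113). BCHE, butyrylcholinesterase, was 2.21-fold lower (log2 fold change -1.14, SE 0.11, adjusted p = 0.00284). IGFBP5, which binds insulin-like growth factors, was 2.01-fold lower (from 10.64 ± 0.08 to 9.63 ± 0.07, SD, n = 3 each, adjusted p = 0.00113). The other 7 of the 10 largest falls belonged to RNA genes that encode no protein. They were RNU5D-1 (log2 fold change -1.96), RNVU1-15 (-1.45), DLEU2L (-1.25), SNORD20 (-1.16), RNU5F-1 (-1.06), SNORA28 (-1.05) and RNU4-2 (-1.03). With GFP, RNU5F-1 (4.23), SNORD20 (5.46), RNU4-2 (5.58), SNORA28 (5.76) and also BCHE (6.13) lay below the median probe set level of 6.73. RNVU1-15 (8.55), RNU5D-1 (8.05) and DLEU2L (7.09) lay above it. Small nuclear RNA genes have near-identical copies, so the assignment of these values to a particular copy is uncertain. RNU4-2 lost its call without GFP replicate 1 (adjusted p = 0.0662), GFP replicate 2 (0.0895) or SETDB1 replicate 1 (0.0518), and the other 9 kept theirs without each array in turn. Further protein-coding genes with large falls, chosen after their values were seen, were SEMA6A (1.90-fold lower), CFAP20DC (1.86-fold), SORL1 (1.86-fold), GXYLT2 (1.82-fold), SULT1C2 (1.80-fold), IFT81 (1.78-fold) and TMEM229B (1.77-fold).

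Pigment cell genes were among those that fell. Of 25 measured genes of melanocyte differentiation and pigmentation, 12 fell and 1 rose over all genes tested, and 16 fell and 1 rose when adjusted over the list alone. The median log2 fold change was -0.21 (camera adjusted p = 1.31e-08, and adjusted p = 0.281 with an estimated correlation). EDNRB, the endothelin receptor of the melanocyte lineage, was 1.53-fold lower (log2 fold change -0.62, adjusted p = 0.00302). MITF, the master transcription factor of melanocytes, was 1.42-fold lower, at 12.02 ± 0.08 with GFP and 11.51 ± 0.06 with SETDB1 (SD, n = 3 each; adjusted p = 0.00438). SLC45A2 and SLC24A5, transporters of the melanosome, were 1.39-fold and 1.34-fold lower. The gene that rose was PAX3 (log2 fold change 0.27, adjusted p = 0.0285, chosen after its value was seen), whose call was lost without GFP replicate 1 (adjusted p = 0.0728), GFP replicate 3 (0.0641) or SETDB1 replicate 1, 2 or 3 (0.0789, 0.0859 and 0.0831). Without each array in turn, 6 (SETDB1 replicate 2) to 10 members of the list were called lower. In the list of neural crest and undifferentiated melanoma genes, 22 were measured, of which 1 rose and 2 fell, and 4 rose and 5 fell when adjusted over the list alone. The list had a median of 0.08 (0.04 to 0.09 without each array in turn) and a camera adjusted p of 0.695. RXRG, a retinoid receptor, was 1.67-fold lower, NGFR, the nerve growth factor receptor of neural crest cells, was 1.37-fold higher, and TFAP2A was 1.25-fold lower.

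Genes for replication-dependent histones were also among those that fell. Of 31 measured, 18 fell and none rose, 25 fell when adjusted over the list alone, and the median log2 fold change was -0.28 (camera adjusted p = 4.01e-14, and adjusted p = 0.281 with an estimated correlation). The linker histone genes H1-3 and H1-2 were 1.56-fold and 1.46-fold lower, H2AC4 was 1.49-fold lower and H3C1 was 1.34-fold lower. Histone genes share much of their sequence, so a value may hold signal of several copies. Without SETDB1 replicate 2, 10 members were called, without SETDB1 replicate 3, 11, and without GFP replicate 1, 12. The class of small nucleolar RNA genes, tested after the largest falls were seen, held 68 of 175 genes lower and 0 higher, with a median of -0.33 (camera adjusted p = 1.38e-21 over 5 classes, and adjusted p = 0.173 with an estimated correlation). The median in each array fell steadily from GFP replicate 1 to SETDB1 replicate 3, so a drift along this order cannot be told apart from the group. The small nuclear RNA genes held 14 of 20 lower and 0 higher, with a median of -0.57 (camera adjusted p = 1.88e-13, and adjusted p = 0.0833 with an estimated correlation). The number of small nucleolar RNA genes called lower was 42 without GFP replicate 1, 45 without GFP replicate 2, 76 without GFP replicate 3, 59 without SETDB1 replicate 1, 26 without SETDB1 replicate 2 and 36 without SETDB1 replicate 3. Among 173 microRNA genes 7 rose and 1 fell (median 0.08, camera adjusted p = 0.0175, and adjusted p = 0.354 with an estimated correlation). Among 632 long noncoding RNA genes 25 rose and 25 fell (median 0.09, camera adjusted p = 0.00149, and adjusted p = 0.346 with an estimated correlation). The microRNA and long noncoding classes were not matched on expression level. With all genes in 10 equal bins by level, bin 1 the dimmest, the medians of bins 2 to 4 were also 0.08 to 0.11. A rise particular to these classes was thus not shown.

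**Figure D2:**
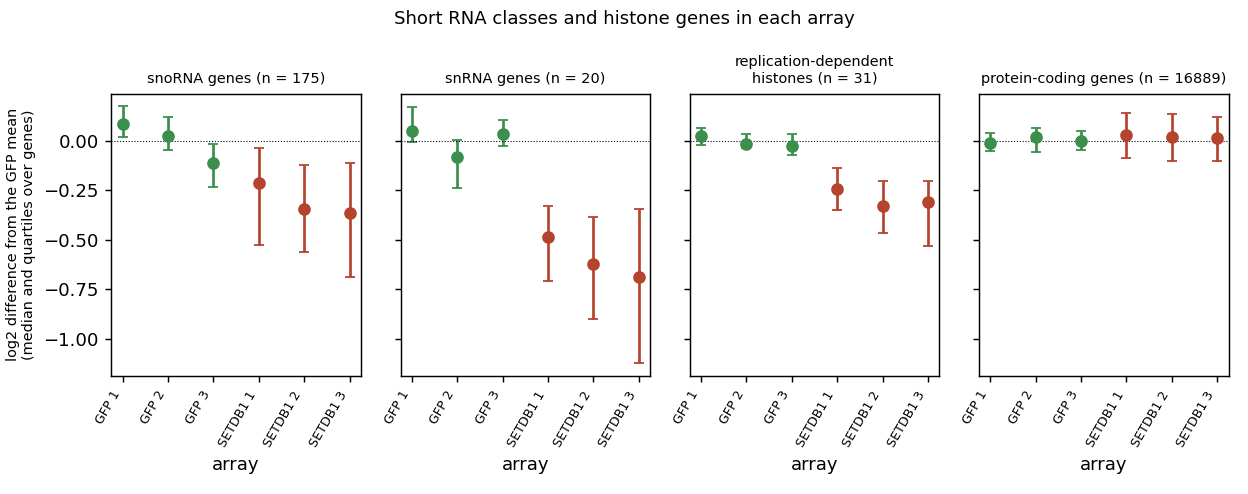
Log2 difference of each gene from its mean over the GFP arrays (vertical axis), shown for each array (horizontal axis) as the median (point) and quartiles (bars) over the genes of a class, with GFP arrays in green and SETDB1 arrays in red. The small nuclear RNA medians lie between -0.49 and -0.69 in the SETDB1 arrays and between -0.08 and 0.05 in the GFP arrays. The small nucleolar RNA medians lie closer and fall from each array to the next in the order shown. They are 0.09, 0.02 and -0.11 in the GFP arrays and -0.21, -0.34 and -0.37 in the SETDB1 arrays. A drift along this order runs together with the group and was not tested. The protein-coding medians lie between -0.01 and 0.03 in all arrays.

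Few mitotic genes were called. Of 31 measured genes of G2/M and mitosis, 4 fell and none rose, also when adjusted over the list alone, and the median was -0.06 (camera adjusted p = 0.00237, and adjusted p = 0.525 with an estimated correlation). The median ranged from -0.09 to -0.05 without each array in turn. After cyclic loess it was -0.04 (camera adjusted p = 0.0479), and among random lists matched on expression level the main median lay at percentile 8.01. The mitotic kinesin KIF20A was 1.30-fold lower and CCNB1, cyclin B1, was 1.15-fold lower. KIF20A lost its call without SETDB1 replicate 2 (adjusted p = 0.0542), and the other 3, CCNB1, ASPM and DLGAP5, lost theirs without each of the 6 arrays in turn, with adjusted p of up to 0.138, 0.129 and 0.144. Of 32 measured genes of G1/S and DNA replication, CCNE1, cyclin E1, was called lower (log2 fold change -0.23, adjusted p = 0.0482) and none was called when adjusted over the list alone. CCNE1 lost its call without each of the 6 arrays in turn, with adjusted p of up to 0.129. The G1/S calls turned with scaling. They were 3 higher and 0 lower after quantile normalization, 2 and 0 after cyclic loess, and 0 and 2 with arrays centred on their medians. The list had a median of 0.04 (-0.0045 with arrays centred on their medians, percentile 99.5 of matched random lists) and a camera adjusted p of 0.435, but was called higher after cyclic loess (median 0.06, adjusted p = 0.0318).

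Sterol synthesis genes were among those that rose. Of 19 measured genes of cholesterol biosynthesis and uptake, 8 rose and none fell, 10 rose when adjusted over the list alone, and the median was 0.19 (camera adjusted p = 3.32e-05, and adjusted p = 0.525 with an estimated correlation). HMGCS1, a synthase of the mevalonate pathway, was 1.51-fold higher (log2 fold change 0.59, adjusted p = 0.00345). MSMO1 was 1.36-fold, SQLE 1.30-fold and IDI1 1.27-fold higher, and each encodes an enzyme on the route to cholesterol. The number called higher was 4 without SETDB1 replicate 2 or SETDB1 replicate 3 and 5 without GFP replicate 3 or SETDB1 replicate 1, and 4 with arrays centred on their medians.

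The matrix, MAPK and inflammatory lists had medians above 0, with members going both ways. Of 31 measured genes of the extracellular matrix and TGF-beta response, 4 rose and 1 fell, 10 rose and 1 fell when adjusted over the list alone, and the median was 0.11 (camera adjusted p = 0.00365, and adjusted p = 0.281 with an estimated correlation). ACTA2 was 1.67-fold, THBS1, the matrix protein thrombospondin-1, 1.45-fold and CCN2, a connective tissue growth factor, 1.30-fold higher. SPARC, a collagen-binding matrix protein, was 1.17-fold lower (adjusted p = 0.0306), a call lost without 5 of the 6 arrays, with adjusted p of up to 0.1004. Of 22 measured genes of MAPK pathway output, 6 rose and 2 fell, 11 rose and 2 fell when adjusted over the list alone, and the median was 0.15 (camera adjusted p = 0.0197, and adjusted p = 0.703 with an estimated correlation). The immediate-early gene FOS was 1.30-fold higher and the ETS factor ETV5 was 1.30-fold lower. The MAPK list lost its call without GFP replicate 1 (adjusted p = 0.0713), GFP replicate 3 (0.0506) or SETDB1 replicate 3 (0.0808), and its members called higher numbered 2, 3, 2, 3 and 1 without GFP replicates 1 and 3 and SETDB1 replicates 1, 2 and 3. Of 25 measured inflammatory and NF-kB response genes, 4 rose and none fell, 7 rose and 1 fell when adjusted over the list alone, and the median was 0.09 (camera adjusted p = 0.0197, and adjusted p = 0.281 with an estimated correlation). CXCL8 led this list, followed by the transcription factor IRF1 (1.28-fold, adjusted p = 0.0272), whose call was lost without 5 of the 6 arrays, with adjusted p of up to 0.0715. The inflammatory list lost its call without SETDB1 replicate 3 (adjusted p = 0.0757) and with members at or above the median probe set level only (0.175). Its members called higher numbered 2 without GFP replicate 1 or 2 and 1 without any of the SETDB1 replicates.

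Few genes of energy metabolism and translation were called in the main fit. With an intensity trend and a robust prior, 11 oxidative phosphorylation subunits and 12 ribosomal protein genes were called lower and 0 higher. Of 66 measured oxidative phosphorylation subunits 3 fell, 1 when adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.000778, and adjusted p = 0.525 with an estimated correlation). COX7C, a subunit of cytochrome oxidase, was 1.33-fold lower. The number called lower was 2 without SETDB1 replicate 1 and 1 without each of the other arrays, and 1 was called higher without GFP replicate 1. Without SETDB1 replicate 3 the median was -0.05. Of 64 measured cytosolic ribosomal protein genes 2 fell, 1 when adjusted over the list alone, with a median of -0.05 (camera adjusted p = 0.00662, and adjusted p = 0.281 with an estimated correlation). RPL22L1 was 1.31-fold lower, a call lost without SETDB1 replicate 2 (adjusted p = 0.0521), and RPL31 lost its call without each of the 6 arrays, with adjusted p of up to 0.125. No ribosomal gene was thus called without SETDB1 replicate 2 and 1 without each of the others, and the median was -0.03 without SETDB1 replicate 3. The ribosomal list was not called among genes at or above the median probe set level (adjusted p = 0.117).

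**Figure D3:**
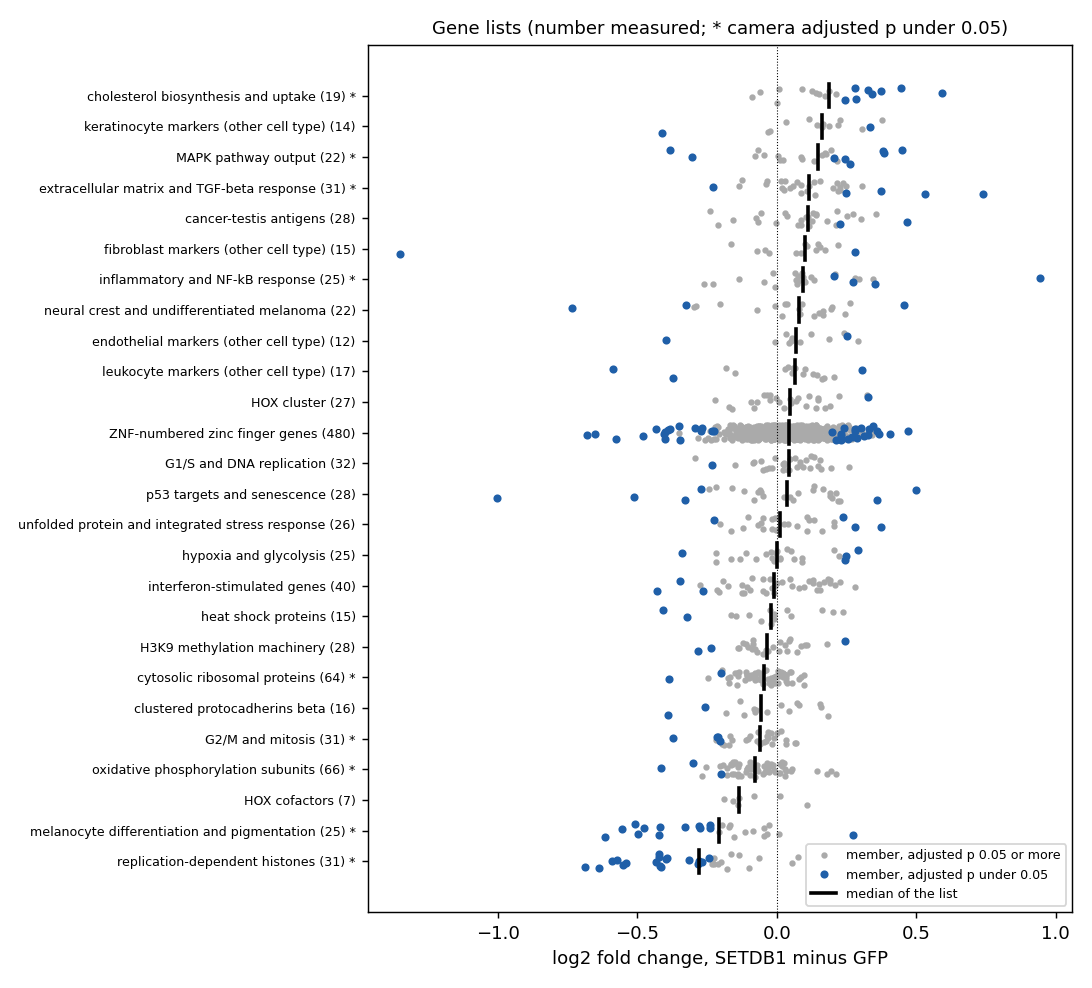
Log2 fold change, SETDB1 minus GFP (horizontal axis), of each measured member (points) of the 26 gene lists (vertical axis, with the number measured), with the median as a bar, members past the adjusted threshold in blue and an asterisk for lists past the camera threshold. The lowest median is that of the histones (-0.28) and the highest that of cholesterol biosynthesis and uptake (0.19).

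The HOX genes, developmental transcription factors that the study is known to have singled out on these arrays, were not called as a group. Of 39 listed, 27 were measured and the others were not analysed here. HOXA2 was the only HOXA gene measured, so the test says nothing about the rest of that cluster. HOXD10 was the gene that rose (1.25-fold, log2 fold change 0.33, SE 0.06, adjusted p = 0.0156), none fell, and the same counts of 1 and 0 held when adjusted over the list alone. HOXD10 lost its call without SETDB1 replicate 1 (adjusted p = 0.0501), and 2 HOX genes were called higher without GFP replicate 3. The list's median was 0.05 (camera adjusted p = 0.435), but 0.01 without SETDB1 replicate 1, -0.0017 with arrays centred on their medians and -0.02 among members at or above the median probe set level. Because the study chose this list from these samples, it is not independent evidence of a direction. HOXD13 (log2 fold change -0.17, adjusted p = 0.0717), HOXD3 (0.32, 0.0820) and HOXB1 (0.22, 0.0927) missed the threshold. The 7 measured HOX cofactors had a median of -0.14 (-0.09 without SETDB1 replicate 1, camera adjusted p = 0.174), and none was called over all genes or when adjusted over the list alone. Of these, PKNOX2 came nearest (log2 fold change -0.19, adjusted p = 0.0864).

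Lists close to the known work of SETDB1, which silences genes with zinc finger partners, were not called. Of 28 measured members of the machinery of H3K9 methylation, 1 rose and 2 fell, also when adjusted over the list alone, with a median of -0.04 (-0.02 without GFP replicate 2 and 0.0016 after quantile normalization; camera adjusted p = 0.408). The demethylase genes KDM3A (1.19-fold higher, adjusted p = 0.0347) and KDM4C (1.22-fold lower, adjusted p = 0.0367) went opposite ways, and each lost its call without 5 of the 6 arrays, with adjusted p of up to 0.115 and 0.114. CBX5, the third, lost its call without each of the 6 arrays, with adjusted p of up to 0.118, so that none of the list was called without GFP replicate 1 or any of the SETDB1 replicates. Of 480 zinc finger genes with ZNF symbols, 20 rose and 17 fell, 9 and 12 when adjusted over the list alone, with a median of 0.04 (-0.0023 with arrays centred on their medians; camera adjusted p = 0.295). The zinc finger list was called without GFP replicate 2 (adjusted p = 0.0324) and, with a median of 0.05, among genes at or above the median probe set level (adjusted p = 0.00485). Its calls were 5 higher and 12 lower without GFP replicate 1, 25 and 8 without GFP replicate 2, 12 and 13 without GFP replicate 3, 3 and 6 without SETDB1 replicate 1 or 3, and 2 and 4 without SETDB1 replicate 2. Their balance turned with scaling, at 6 higher and 21 lower with arrays centred on their medians and 43 higher and 14 lower after quantile normalization. ZNF860 was 1.60-fold lower and ZNF234 was 1.32-fold lower. Of 16 clustered protocadherin beta genes, 2 fell and none rose, also when adjusted over the list alone (median -0.05, camera adjusted p = 0.408, percentile 0.12 of matched random lists). The protocadherin median was -0.0105 without GFP replicate 3, -0.0127 without SETDB1 replicate 1 and -0.0112 without SETDB1 replicate 2, and no member was called without either of the latter. It was -0.09 without GFP replicate 2 or SETDB1 replicate 3. PCDHB2 was 1.31-fold lower, a call lost without SETDB1 replicate 1 (adjusted p = 0.0568) or SETDB1 replicate 2 (0.0691). Of 28 measured cancer-testis antigens, 2 rose and none fell, also when adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.0601). MAGEA4 was 1.38-fold higher, but not past the threshold without GFP replicate 1, GFP replicate 3, SETDB1 replicate 2 or SETDB1 replicate 3 (adjusted p = 0.0582, 0.0524, 0.0512 and 0.0613). The cancer-testis list was called without GFP replicate 1 (adjusted p = 0.0385), GFP replicate 3 (0.0421), SETDB1 replicate 1 (0.0309) or SETDB1 replicate 3 (0.0271), with arrays centred on their medians (0.0335), and in the fit of all probe sets (0.0196). It was not called without GFP replicate 2 (median 0.06, adjusted p = 0.239) or SETDB1 replicate 2 (0.07, 0.211), after quantile normalization (adjusted p = 0.207), or after cyclic loess (median 0.05, adjusted p = 0.285), and no member was called without GFP replicate 3, SETDB1 replicate 2 or SETDB1 replicate 3.

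Stress and interferon lists were not called either. Of 40 interferon-stimulated genes, 3 fell and none rose, also when adjusted over the list alone, with a median of -0.0086 (camera adjusted p = 0.695) that was 0.03 without GFP replicate 2 and 0.02 without SETDB1 replicate 3. The number of interferon genes called lower was 1 without SETDB1 replicate 2 and 2 without GFP replicate 1 or SETDB1 replicate 1 or 3, and 1 was called higher without GFP replicate 2 or 3. PARP9 was 1.35-fold lower. Of 28 p53 target and senescence genes, 2 rose and 4 fell, 6 and 6 when adjusted over the list alone, with a median of 0.04 (0.02 to 0.06 without each array in turn), a mean of -0.02, camera's direction down and a camera adjusted p of 0.798. IGFBP5 was 2.01-fold and CCNG1, cyclin G1, 1.43-fold lower, while GADD45A, a DNA damage response gene, was 1.41-fold higher. Of 26 genes of the unfolded protein and integrated stress response, 3 rose and 1 fell, also when adjusted over the list alone (median 0.01, -0.03 with arrays centred on their medians, 0.03 without SETDB1 replicate 2, 0.0069 without SETDB1 replicate 3, camera adjusted p = 0.533). The number of stress response genes called higher was 1 without GFP replicate 1 or SETDB1 replicate 1 or 3, and 0 without SETDB1 replicate 2. With arrays centred on their medians 1 was called higher and 1 lower. Among the fits without 1 array, the member that fell kept its call only without GFP replicate 3. TRIB3, a pseudokinase induced by stress, was 1.29-fold higher, a call lost without SETDB1 replicate 2 (adjusted p = 0.0524). Of 15 heat shock protein genes, 2 fell and none rose, also when adjusted over the list alone (median -0.02, 0.0020 after quantile normalization, camera adjusted p = 0.405), and HSPA4L was 1.33-fold lower. The heat shock median ranged from -0.03 to -0.0074 without each array in turn, and only 1 member was called without GFP replicate 2 or SETDB1 replicate 1 or 3, where HSPB8 lost its call (adjusted p of up to 0.0646). Of 25 hypoxia and glycolysis genes, 3 rose and 1 fell, 5 and 3 when adjusted over the list alone, with a mean of 0.0088, camera's direction down and a camera adjusted p of 0.863. No hypoxia gene was called higher without GFP replicate 1 or any of the SETDB1 replicates, or with arrays centred on their medians, where 3 were called lower. The collagen-modifying enzyme gene P4HA1 was 1.26-fold lower.

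Markers of other cell types went both ways. Of 15 fibroblast markers, LUM fell and PDGFRB rose (1.21-fold), also when adjusted over the list alone, with a median of 0.10, a mean of -0.01 and a camera adjusted p of 0.448. The fibroblast median ranged from 0.03 without SETDB1 replicate 1 to 0.16 without SETDB1 replicate 3, and was 0.02 after cyclic loess. Of 17 leukocyte markers 1 rose and 2 fell, also when adjusted over the list alone (median 0.07, 0.04 to 0.09 without each array in turn, camera adjusted p = 0.710), with FCER1G (log2 fold change -0.59) and CD68 (-0.37) lower. Of 12 endothelial markers 1 rose and 1 fell, 2 and 1 when adjusted over the list alone (median 0.07, 0.03 to 0.11 without each array in turn, camera adjusted p = 0.229), with the growth factor receptor KDR 1.32-fold lower. Of 14 keratinocyte markers 1 rose and 1 fell, 2 and 1 when adjusted over the list alone (median 0.16, camera adjusted p = 0.0777), with CDH1, E-cadherin, 1.33-fold lower. The keratinocyte list was called without GFP replicate 3 (adjusted p = 0.0124), with arrays centred on their medians (0.0335), and in the fit of all probe sets (0.0340). It was further from a call without GFP replicate 2 (median 0.10, adjusted p = 0.239), after quantile normalization (adjusted p = 0.273) and after cyclic loess (0.285). It had no called member without GFP replicate 2 or any of the SETDB1 replicates, and 3 called higher without GFP replicate 3. PDGFRB lost its call without SETDB1 replicate 1 (adjusted p = 0.0666), 2 (0.0514) or 3 (0.0549), KDR without SETDB1 replicate 2 (0.0514), and CDH1 and PKP1, the keratinocyte marker that rose, without 5 of the 6 arrays, with adjusted p of up to 0.0890 and 0.145. The endothelial marker that rose, ROBO4, lost its call without each of the 6 arrays and the leukocyte marker that rose, ITGAM, without 5, with adjusted p of up to 0.111 and 0.118.

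Calls were spread unevenly over expression levels. Below the median probe set level of 6.73, where 37.9% of the genes lay, were 300 of the 674 higher calls (44.5%) and 149 of the 1389 lower calls (10.7%). With genes put into 10 equal bins by level, bin 1 the dimmest, the median log2 fold change was 0.11 in bin 4 and -0.05 in bin 8. Of the 26 lists, camera called 9, 4 higher and 5 lower. With an estimated correlation camera called 0 of 26, with 4 lists at an unadjusted p under 0.05, and fry, which tests only whether a list's own genes move one way, called 6.

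**Figure D4:**
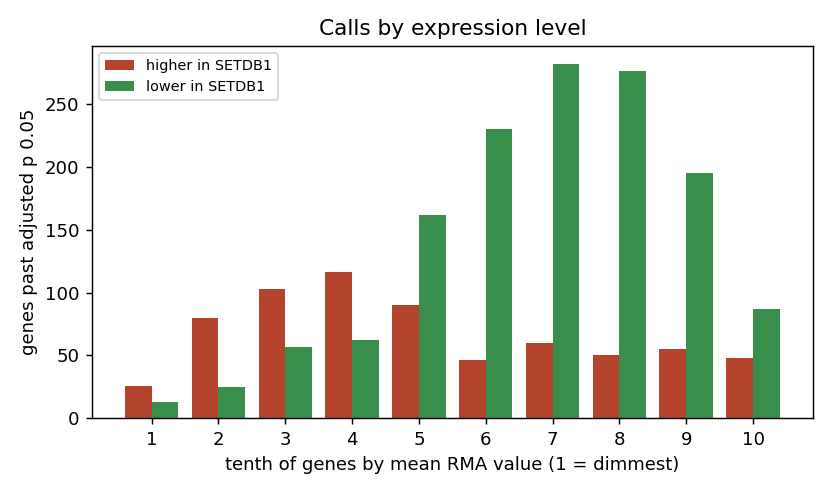
Number of genes past the adjusted threshold (vertical axis), higher (red) or lower (green) in the SETDB1 arrays, in 10 equal bins of genes ordered by mean RMA value (horizontal axis, 1 the dimmest). Higher calls outnumber lower ones in bins 1 to 4, and in bin 7 there are 60 higher and 282 lower calls.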

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

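Of the tests in this part, those of the S phase and of a smaller share of melanoma cells were chosen only after the result was seen, as were the classes of small RNA genes and cyclic loess.

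Signal outside the main measurement appeared in the 12083 probe sets that the annotation table does not list. In a fit of all 33297 probe sets, 19 of them were higher and 112 lower in the SETDB1 arrays than in the GFP control arrays, past an adjusted p of 0.05.

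The small nucleolar RNA genes fell by a median of 0.33 and the replication-dependent histones by a median of 0.28 on the log2 scale. Many small nucleolar RNAs are cut from introns, so lower transcription of their host genes was tested first. Hosts were measured genes that contain the small RNA gene by position, on either strand. For 81 of them with a measured host the median was -0.39, while the 61 hosts had a median of 0.0075 (95% interval -0.01 to 0.03). That interval comes from resampling hosts, so it leaves out the spread between arrays. The host RNA levels argue against lower host transcription, which was not itself measured. Poorer recovery of the shortest RNA may contribute and cannot be told apart from an effect of SETDB1. Across small nucleolar and small nuclear RNA genes, Spearman's rho of RNA length and change was 0.0372 (permutation p = 0.605), which reached neither direction. These classes are all short. Median lengths were 80 bases for SNORD and 134 for SNORA genes, both small nucleolar, and 145 for small nuclear RNA genes. A loss shared by all of them would leave no such trend, so this test cannot decide. For the histones, fewer cells in S phase might lower the G1/S list too, by an amount not known here. The G1/S median was 0.0427 (95% interval -0.0026 to 0.08, from resampling genes), and -0.0045 with arrays centred on their medians. The interval leaves out the spread between arrays, and a small fall could go unseen, so this test cannot decide. Cell cycle phase and DNA synthesis were not measured. The G2/M list had a median of -0.06 (camera adjusted p = 0.00237, and 0.525 with an estimated correlation). Fewer cells in S phase thus stay open. A difference in RNA without long poly(A) tails and an effect of SETDB1 stay open too, untested.

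Dim genes tended to be higher and brighter genes lower in the SETDB1 arrays, with a difference of 0.17 between the medians of bins 4 and 8 when genes are put into 10 equal bins by level. A single array does not account for it, since the difference stayed at 0.10 or more without each array in turn, lowest without GFP replicate 2. An offset between arrays that varies with intensity may account for many of the dim higher calls: after cyclic loess, which removes such an offset, 33.3% of the 300 stayed past the threshold (100 genes). A rise of many dim transcripts with SETDB1 would be removed by the same step, so it stays open.

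The melanocyte and pigmentation genes had a median of -0.21, with a camera adjusted p of 0.281 at an estimated correlation. After cyclic loess the median was still -0.21 (camera adjusted p = 7.80e-08), which argues against the intensity offset, and without each array in turn it was -0.20 or lower, which argues against a single array. If a smaller share of melanoma cells lowered the members alike, few of their intervals would exclude the list's median. In 48% of the members (12 of 25) the 95% interval excluded it, 5 above it and 7 below. The members differ in level and RMA compresses changes of dim genes, so unequal falls cannot decide against this cause. An effect of SETDB1 on the pigment programme is a hypothesis that may explain the fall, found and tested on the same data. A smaller share of melanoma cells stays open beside it. Differences between the cultures in density or growth, on which the labels say nothing, were not tested and stay open too.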

How the results depend on the processing

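No gene called in the comparison took the opposite sign in any setting. In most settings none could. The groups of all 2063 called genes did not overlap, so leaving out or weighting an array cannot reverse a sign. Several other settings kept the same fold changes. Only the settings that rescaled the arrays or averaged probe sets could have turned a sign. Counting each named gene in each alternative, the side of the threshold was kept 2043 times, a call was lost 419 times and one was gained 47 times. For lists these numbers were 419, 18 and 12, with 16 changes of sign and 3 more for the HOX list, all in lists that were not called. A list's direction is the sign of its median, a choice made after seeing the data. With the replicate block, 877 genes were called (201 higher, 676 lower), of which 854 were called without it, and it ended no list's call. The numbers do not pair the samples, since deviations from group means correlated at 0.04, -0.15 and -0.15 for numbers 1, 2 and 3, and 1 of 6 arrays correlated best with its own number. Without each array in turn the count ranged from 556 (SETDB1 replicate 2) to 1700 (GFP replicate 3), with 110 to 644 higher and 446 to 1056 lower; 117 to 167 genes changed at least 1.5-fold, 8 to 10 lists were called, the SETDB1 change was 1.33 to 1.47 and the HOX median 0.01 to 0.05.

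Where no cause is named, the cause was not tested. Centring arrays on their medians gave 347 higher genes. An intensity trend with a robust prior gave 3119 genes, 1093 of them higher. All probe sets together gave 741 (125 higher, 616 lower). That fit had more tests to adjust for and held other probe sets, and which of these lowered the count was not tested. An adjusted p of 0.1 gave 3750, and a 2-fold limit 11 in place of 155. Protein-coding genes alone gave 96 at least 1.5-fold changed, since small RNA genes were left out. Camera with an estimated correlation called 0 lists, with 4 at an unadjusted p under 0.05, and fry 6. The inflammatory list lost its call with bright members only (adjusted p = 0.175) and the ribosomal list with dim genes left out (0.117).

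Medians changed sign with arrays centred on their medians for the HOX (-0.0017), zinc finger (-0.0023), G1/S (-0.0045), p53 (-0.0107) and unfolded protein (-0.0349) lists, which the construction shows, since centring shifted all genes down. Quantile normalization turned the H3K9 machinery (0.0016), heat shock (0.0020) and hypoxia (0.0415) lists. Array weights turned the interferon (0.0120) and hypoxia (0.0104) lists, and cyclic loess the hypoxia list (0.0232). Cyclic loess also called the G1/S list higher (adjusted p = 0.0318). With dim genes or dim members left out, the HOX median was -0.0234 and the p53 median -0.0125. Without each array in turn the interferon median ranged from -0.0283 to 0.0324, above 0 without GFP replicate 2 or SETDB1 replicate 3 (0.0245), and the hypoxia median from -0.0055 to 0.0136, above 0 without GFP replicate 2 or SETDB1 replicate 2 (0.0039). Signal over background limits dim genes, whose changes RMA compresses.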

Other observations

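The lists in this part were written after IFT81, BBS5, WDPCP, TMEM67, MYOF, AMOTL2, CCN2 and GADD45A had been seen among the called genes.

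A few genes of the primary cilium, the sensory antenna of the cell, were called lower in the SETDB1 arrays. IFT81, a component of intraflagellar transport, was 1.78-fold lower (8.30 ± 0.07 with GFP, 7.47 ± 0.12 with SETDB1, SD, n = 3 each, limma adjusted p = 0.00246). Of 53 other genes of cilium assembly and transport, which had not been looked at before, 6 fell and none rose. These were TMEM17 (log2 fold change -0.47, SE 0.05), BBS2 (-0.46, SE 0.09), BBS9 (-0.46, SE 0.10), TMEM237 (-0.28, SE 0.06), CEP41 (-0.28, SE 0.07) and IFT25 (-0.25, SE 0.06). The median of the 53 was -0.11 (camera adjusted p = 3.83e-06 over the 2 lists, 3.11e-05 after cyclic loess), but the adjusted p was 0.398 with an estimated correlation and 0.0724 with fry. Without each array in turn the median lay between -0.15 and -0.08. A lower level of primary cilium genes with SETDB1 is a hypothesis that fits the camera test and may not hold if the genes vary together between samples. Cilia themselves were not measured.

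MYOF, AMOTL2, CCN2 and GADD45A led to the hypothesis that targets of the transcription factors YAP and TEAD might be higher. Of the 16 other targets 2 rose and none fell. Their median was 0.0240 (camera adjusted p = 0.537) and -0.03 after cyclic loess, and members going both ways leave the hypothesis undecided.

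The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2063 genes, 155 of them at least 1.5-fold changed, and 1 of the 10 splits, the real one, reached either number. Each of the other splits mixes the groups, with 2 arrays of 1 group and 1 of the other on each side. It keeps part of the real difference and moves the rest into the spread within its sides. Fewer gene calls and smaller list medians in those splits follow in part from this design and are no test against chance. The highest of the other splits was 0 for both by limma. Up to 1100 of their genes had an unadjusted p under 0.05, against 5625 in the real split. For gene lists the real split called 9 and the highest of the others also 9, so 2 of the 10 splits reached that number. The medians of the 9 called lists compare with the largest size in another split as follows. The histone median of -0.28 stood against 0.15, melanocyte -0.21 against 0.11, cholesterol 0.19 against 0.11, MAPK 0.15 against 0.08 and inflammatory 0.09 against 0.06. The margins were narrower for oxidative phosphorylation (-0.08 against 0.05), ribosomal proteins (-0.05 against 0.03) and G2/M (-0.06 against 0.05), and the extracellular matrix median of 0.115 was nearly matched (0.108).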
